A study of Mus musculus with 34 samples.

How the data were processed

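The series holds 34 mouse RNA samples from C57BL/6 thymus, bone marrow and culture: 30 bulk libraries and 4 single-cell libraries. Sorted DN3 thymocytes came from WT mice (3 libraries), from mice with a floxed DNS element and CD2-cre (ΔDNS, 2), from mice with a floxed N1c element and CD2-cre (ΔN1c, 2) and from DNSe-/- mice (ΔDNSe, 2). DN3 cells grown with the Notch ligand DLL1 gave 3 WT and 3 ΔDNSe libraries. The B lineage set holds bone marrow proB, large preB and small preB cells and CD19+ cells from the thymus of ΔDNS mice, 2 libraries each. A series of 7 WT stages from ETP to CD4 and CD8 single positive cells has 1 library per stage, and sorted ETPs gave 2 WT and 2 ΔDNSe single-cell samples. The labels do not define DNS or N1c. One WT single-cell sample is described as DN3 in one label and as ETP in its title, and it was grouped by its title.

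The deposited bulk tables hold signal values: per the file headers, read counts per RefSeq gene were scaled so that every column of a table has the same total, with 1 transcript per gene in the layout of HOMER. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.3 and aligned with STAR to mm10; filters and strand use are not stated. The labels' protocols name 2 library kits without saying which sample had which. In every column, values up to 60 steps of the smallest value were whole multiples of that step within 0.006, so whole reads could be recovered for 100% of the values checked. No T cell receptor or immunoglobulin segments are listed in the bulk tables. The single-cell files hold UMI counts deposited for all barcodes, unfiltered; the counting software is not stated per the labels. The authors' deposited tables of cluster markers hold log2 fold changes of each cluster against the other cells of the same sample, for 13 clusters in replicate 1 and 12 in replicate 2; how cells were filtered and clustered is not stated.

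Depth in recovered gene reads was 16.744 to 27.293 M per ex vivo DN3 library, 20.529 to 31.012 M per in vitro library, 19.195 to 37.542 M per B lineage library and 21.83 to 33.133 M per stage library. The design chosen before the data were examined assumed raw counts in the bulk tables, with limma-trend on log2(value + 1) as the fallback for normalized values; the values were normalized, so the fallback is the main bulk test (limma 3.58.1, genes of mean value at least 1, Benjamini-Hochberg adjusted p under 0.05). One fit was made over the 9 ex vivo DN3 libraries, another over the 6 in vitro libraries and one over the 8 B lineage libraries, each with group as its only term. CPM are recovered reads per M (mega) recovered gene reads, and values called scaled reads are the deposited ones. Strand use is not stated, so reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical copies may have been split between them.

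Single cells were called as barcodes with at least 0.1 of the 99th percentile of the UMIs of the top 3000 barcodes of their sample, at least 500 genes and at most 10% mitochondrial UMIs. The automatic scrublet threshold marked 0.04 to 0.42% of cells and had therefore not worked; after the data were seen, the cells with the highest scores were removed instead, at an expected rate of 0.8% per 1000 cells called. This left 6795 and 3544 WT cells and 6544 and 3225 ΔDNSe cells, with 42.7, 34.64, 39.92 and 35.24 M UMIs in those cells. The 20108 cells were clustered together (scanpy 1.11.5, 2000 variable genes, 30 principal components, 20 neighbours, leidenalg 0.10.2 at resolution 0.6), giving 16 clusters. A cluster was named from markers fixed in advance when at least 3 of them were detected in at least 10% of its cells at 1.5-fold or more over the other cells, their mean log2 fold was the highest of all classes and above 0, and no other class had more markers among the 10 leading genes of the cluster. Clusters of low depth also needed a marker among the leading genes. The details of this naming rule were set after the data were seen. UMIs were summed per sample, over all cells and over each class with at least 50 cells in every sample, and tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). Class shares are given per sample with exact Clopper-Pearson 95% intervals, which cover counting error only; where a share is 0, the limit is 3 cells of the total.

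Genes named in the text follow a rule: Notch1 and the list of Notch-driven genes; up to 8 genes rising and 8 falling with the largest fold change among those past the threshold with an average log2 CPM of at least 4 and groups that do not overlap, without unnamed gene models, receptor segments and sex genes; and up to 4 members of a described list with the smallest p. Genes named outside the rule are said to be so. In all, 29 gene lists were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists; no list passed with an estimated correlation in any of the 15 sets of list tests, and that adjusted p stands beside each preset list p printed as called. For the stage series, with no replicates and no test, genes were named by size: up to 2 per stage with the largest ratio to the next highest stage among genes of at least 50 CPM.

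Alternatives were DESeq2 1.42.0 and edgeR on recovered reads, RLE and TMM scaling, other pseudocounts and filters, fits of only the groups compared, the replicate number as a block, other cell calling and clustering settings, cells thinned to 2000 UMIs and the removal of each replicate in turn. The tests were tried on simulated counts with 50 genes changed at each of 4 fold sizes. The adjusted p depends on how many genes change, so the rates below do not carry over to comparisons with far more called genes. For ΔDNSe against WT ex vivo (15190 genes), limma recovered 14% of the genes changed 1.5-fold, 78% at 2-fold and 96% at 4-fold. For the in vitro comparison (15574 genes) it recovered 56%, 98% and 100%, and for thymic B against proB (15987 genes) 10%, 62% and 86%. For the single-cell sums (13377 genes), edgeR recovered 4%, 54% and 94%. No duplicate libraries were found. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Read alignment, unannotated transcripts and receptor rearrangements were not analysed here.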

Results

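RNA was sequenced from sorted mouse thymocytes, cultured DN3 cells and B lineage cells to compare WT cells with cells lacking DNA elements tied by the series to Notch1, the receptor that drives early T cell development. The ex vivo DN3 table holds 3 WT, 2 ΔDNS, 2 ΔN1c and 2 ΔDNSe libraries with 16.744 to 27.293 M (mega) gene reads each. The in vitro DN3 table holds 3 WT and 3 ΔDNSe libraries with 20.529 to 31.012 M. The 8 B lineage libraries, 2 per group, hold 19.195 to 37.542 M, and the 7 WT stage libraries, 1 per stage, 21.83 to 33.133 M. The 4 single-cell ETP samples hold 34.64 to 42.7 M UMIs in 3225 to 6795 cells.

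**Figure D1:**
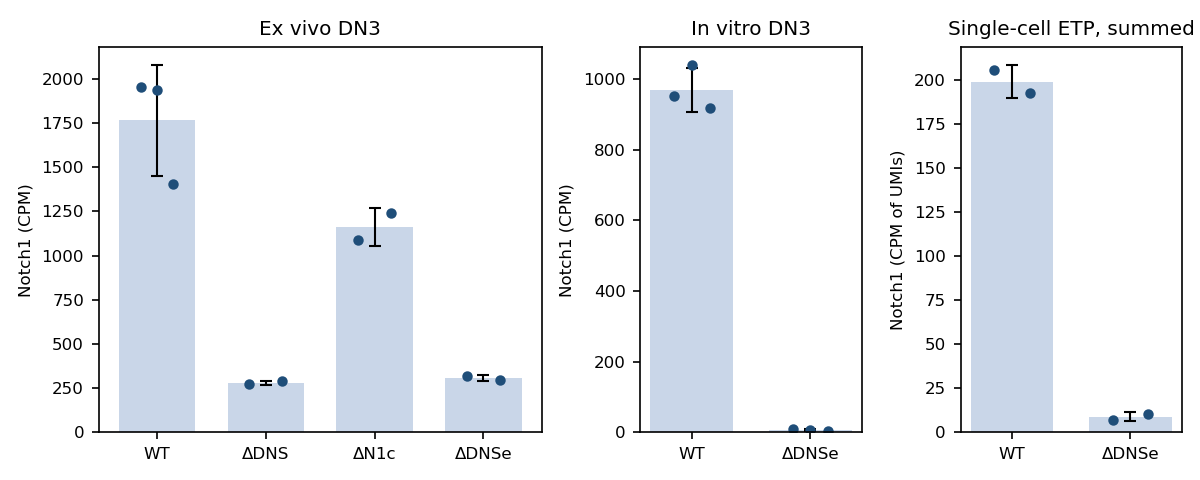
Notch1 level in CPM (y axis) per library (points), with bars at the group mean and error bars of 1 SD, in ex vivo DN3 cells, in vitro DN3 cells and summed single-cell ETPs. Ex vivo WT libraries averaged 1764 CPM, and ΔDNS and ΔDNSe libraries 281.8 and 307.4 CPM.

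The first comparison asks what the CD2-cre deletion of DNS does to DN3 cells. Notch1 (NM_008714) averaged 1764 ± 312 CPM (SD) in 3 WT libraries and 281.8 ± 11.6 CPM in 2 ΔDNS libraries, a log2 fold change of -2.63 ± 0.154 (SE). A pair of noncoding genes beside it fell with it: 0610009E02Rik (log2 -2.55), which overlaps the Notch1 3′ end on the opposite strand, so that their reads cannot be told apart, and Gm35978, just upstream of Notch1, which averaged 121.2 scaled reads in WT and was listed at 0 in both ΔDNS libraries. Mid1, an X-linked gene for a ubiquitin ligase, rose from 120.5 ± 64 to 10140 ± 2550 scaled reads. Nnat (log2 4.02), an imprinted gene, and Blcap (log2 1.34), the gene that contains it on the opposite strand, also rose. The libraries also differed in sex-linked RNA: Xist lay between 0.2418 and 1.018 CPM in WT and at 0.6569 and 4226 CPM in ΔDNS, and at 1664 or more in every ΔN1c and ΔDNSe library. None of the 15 Notch-driven genes passed the test over all genes. Dtx1, a Notch pathway ubiquitin ligase, had a log2 fold change of -0.82 (adjusted p = 0.749), Ptcra, the pre-TCR alpha chain, -0.48 and Il2ra, the CD25 chain, -0.64. Nrarp, a feedback inhibitor of Notch, stood at -0.27, Myc at 0.15 and Hes1 at 0.21. Adjusted over the list alone, 2 were lower. In all, limma called 7 of 15266 genes (3 higher, 4 lower; the remaining one is 2700054A10Rik, lower), with adjusted p = 0.000102 for Notch1. The genes outside Notch1 were named because the count is small, after their values were seen. An unadjusted p under 0.05 was reached by 946 genes. By edgeR on recovered reads the count was 6 (13 with any count kept), by DESeq2 24, without pseudogenes and unnamed gene models 4 and without WT replicate 1 117.

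The second comparison concerns the CD2-cre deletion of N1c. Notch1 averaged 1164 ± 107 CPM in 2 ΔN1c libraries against 1764 ± 312 in WT (log2 -0.59 ± 0.154, adjusted p = 0.0833), which did not pass the test. Ptcra fell by 0.69 on the log2 scale (adjusted p = 0.0395), the only one of the 15 Notch-driven genes past the threshold over all genes, with 2 lower adjusted over the list alone. Il2ra stood at -1.17 (adjusted p = 0.0572), Dtx1 at -0.07 and Nrarp at -0.25. Among the largest rises were the X-linked Mid1 (log2 2.80; 738.4 ± 65.8 scaled reads against 120.5 ± 64 in WT) and Tsix, the antisense RNA of Xist (10.21; 2683 ± 1010 against 1.483 ± 1.29), and Ly6c1, a surface protein of the Ly6 family (2.60; 1113 ± 361 against 178.6 ± 20.7). Others came with a wide spread between the 2 ΔN1c libraries: Ly6a (2.12; 1562 ± 1070 scaled reads), Itgae, the CD103 integrin chain (2.40; 1231 ± 620), Cd163l1, a scavenger receptor of gamma delta T cells (2.32; 3835 ± 2420), and the interferon-induced genes Slfn5 (2.91; 1232 ± 1190) and Oas1a (2.11; 1031 ± 678). Gsr, glutathione reductase, fell from 2705 ± 85.2 to 442.1 ± 96.7 scaled reads (log2 -2.63 ± 0.132, adjusted p = 4.76e-05), and Pclaf, a replication factor, fell by 1.34 (adjusted p = 0.0354). Of the 41 S phase genes none passed over all genes, and 27 were lower adjusted over the list alone (camera, adjusted p = 6.7e-17; adjusted p = 0.584 with an estimated correlation). The list of 16 beta selection genes had 2 members lower (adjusted p = 0.0045; adjusted p = 0.584 with an estimated correlation). By limma, 237 of 15266 genes passed, 172 higher and 65 lower. Xist was high in every ΔN1c library and nearly absent in WT, so these calls were not separated from a sex difference between the mice. The share higher was 72.6% and became 59.8% with RLE scaling, by edgeR on recovered reads 301 genes passed (826 with any count kept), by DESeq2 1223, with no filter on low values 136 and in a fit of only these groups 6. Without ΔN1c replicate 1 the count was 2, without ΔN1c replicate 2 424, and without WT replicates 1, 2 and 3 it was 898, 591 and 44.

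The third comparison asks what germline loss of DNSe does to DN3 cells taken from the mouse. Notch1 averaged 307.4 ± 16.8 CPM in 2 ΔDNSe libraries against 1764 ± 312 in WT (log2 -2.50 ± 0.154, adjusted p = 2.16e-05). Of the Notch-driven genes, Nrarp fell by 1.89 (adjusted p = 0.00063) and Lef1, a transcription factor of T cell development, rose by 0.98 (adjusted p = 0.0205). The other 13 did not pass, among them Dtx1 (log2 -0.42), Hes1 (0.15), Notch3 (0.04), Ptcra (0.06), Il2ra (-0.46), Myc (0.30) and Cd3g (-0.61, adjusted p = 0.062), and adjusted over the list alone 2 were lower and 1 higher. Of 16 genes of multipotent progenitors 6 fell, and 12 were lower adjusted over the list alone (camera, adjusted p = 3.03e-10; adjusted p = 0.238 with an estimated correlation). Spi1, the myeloid and progenitor factor PU.1, fell from 52.78 ± 8.48 to 5.545 ± 0.573 scaled reads, Hhex from 51.35 ± 28.2 to 0.495 and Nfe2 from 672.2 ± 130 to 242.9 ± 58.7. Bcl11a, Lyl1 and Erg were the other members that fell. Of 104 genes at least 20-fold higher at ETP or DN2 than at DN3 in the stage series and with a mean of at least 0.5 CPM in ex vivo WT, 15 fell and 0 rose; 88.5% had a negative log2 fold change, and the median was -0.84. Lists of other cell types and of handling also lay lower: myeloid genes had a median of -1.81 with 1 of 11 called lower (adjusted p = 0.00852; adjusted p = 0.699 with an estimated correlation), 1 of 2 mast cell and basophil genes fell, and none of 11 handling stress genes passed (adjusted p = 0.00935; adjusted p = 0.238 with an estimated correlation). Genes of the double positive transition rose: Cd8a (log2 2.28), Cd8b1 (2.30) and Rorc, the RORγ gene (1.61), 3 of 16 list members (adjusted p = 0.00739; adjusted p = 0.699 with an estimated correlation). The largest rise by the naming rule was in sex-linked RNA: Tsix (log2 10.29) averaged 2930 ± 1520 scaled reads against 1.483 ± 1.29 in WT. Xist was high in every ΔDNSe library and nearly absent in WT, as given above. The effect of genotype was therefore not separated from a sex difference between the mice. Mid1 (log2 5.39), Itgae (2.23) and Cd163l1 (1.88) were also higher. Scin, an actin-severing protein (-2.50), Sytl4 (-2.78) and Muc13, a mucin (-2.34), were lower.

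By limma, 413 of 15266 genes differed between ΔDNSe and WT ex vivo, 106 higher and 307 lower, and by edgeR on recovered reads 407 passed (715 with any count kept) and by DESeq2 820. The ΔDNSe libraries also stood apart in genes that share reads with copies: Acta1, a muscle actin nearly identical to other actins, averaged 46.88 ± 3.8 scaled reads against 565 ± 95.4 in WT, and 55 of 211 pseudogenes tested were lower and 2 higher. Of 409 called genes also listed in the in vitro table, 50.6% differed at least 2-fold in the called direction between in vitro and ex vivo WT cells, against 13.8% of all genes tested. Restricted to genes within 2-fold between those WT groups, 110 genes passed, and in a fit of only WT and ΔDNSe 230 did. Without WT replicate 1 the count was 772, without ΔDNSe replicate 1 112 and without ΔDNSe replicate 2 126.

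Between the deletions, Notch1 was lower in ΔDNS than in ΔN1c by 2.04 on the log2 scale (-2.04, adjusted p = 0.00256), and it did not pass a test between ΔDNSe and ΔDNS (log2 0.12 ± 0.169, adjusted p = 0.789). ΔDNS differed from ΔN1c in 5 genes: Gsr (log2 2.31) and Mid1 (3.76) were higher, and Notch1, 0610009E02Rik and Inppl1, an inositol phosphatase (-3.22), lower, all 5 named after their values were seen. An unadjusted p under 0.05 was reached by 1507 genes, and by edgeR the count was 4 (67 with any count kept), by DESeq2 123, with no filter on low values 11, with pseudocount 0.1 3, among genes within 2-fold between in vitro and ex vivo WT 2 and in a fit of only these groups 134. It was 1 without ΔDNS replicate 1, 3 without ΔN1c replicate 1 and 36 without ΔN1c replicate 2. ΔDNSe differed from ΔDNS in 367 genes, 84 higher and 283 lower. Lef1 (log2 1.34), Ptpn14, a phosphatase (1.52), Hmgb1, a chromatin protein (1.204), Cd8a (2.43) and Rorc (1.205) were higher, and Cpa3, a mast cell and progenitor protease (-2.73), Scin (-2.93), Sytl4 (-3.34) and Acta1 (-3.85) were lower. The ΔDNSe libraries stand apart here too: Hmgb1 averaged 466.6 CPM in them, 202.6 in ΔDNS, 237.9 in ex vivo WT and 667.4 in in vitro WT libraries, and the pseudogene Gm11517 0.9876, 82.92, 77.81 and 0.6736 CPM. Of the 16 progenitor genes 4 were lower and 1 higher (camera, adjusted p = 2.83e-05; adjusted p = 0.718 with an estimated correlation). Among genes within 2-fold between the in vitro and ex vivo WT groups 132 passed, by DESeq2 791 and by edgeR with any count kept 607. Without ΔDNS replicates 1 and 2 the count was 106 and 179, without ΔDNSe replicates 1 and 2 103 and 123, and in a fit of only these groups 1142.

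All 3 deletions were compared with the same WT libraries, which alone makes their fold changes correlate across genes. Between ΔDNS and ΔDNSe the correlation was 0.365, against 0.398 in simulated unchanged groups (covariance 0.111 against 0.0561). Between ΔDNS and ΔN1c it was 0.391 against 0.396 (covariance 0.107 against 0.0561), and between ΔN1c and ΔDNSe 0.149 against 0.407 (covariance 0.0581 against 0.058). ΔN1c and ΔDNSe shared 15 higher and 6 lower genes, where independent lists would share 1.19 and 1.31. Simulated unchanged groups shared 0, but they hold no changed genes, so that count is no baseline for the overlap. ΔDNS and ΔDNSe shared 1 higher and 4 lower genes, against 0.0208 and 0.0804. For ΔDNS and ΔN1c it was 3 higher and 2 lower, against 0.0338 and 0.017. Part of any excess may come from the shared controls, which are too few to split. Tsix, the antisense RNA of Xist, was among the higher genes shared by ΔN1c and ΔDNSe (log2 10.21 and 10.29). The simulation held no difference in sex-linked RNA or library kind, so the overlap was not separated from those. Genes are not independent replicates.

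In culture with DLL1, ΔDNSe DN3 cells lost nearly all Notch1 RNA and much of the RNA of several Notch-driven genes. Notch1 averaged 969 ± 62.2 CPM in 3 WT libraries and 7.095 ± 2.44 CPM in 3 ΔDNSe libraries (log2 -7.14 ± 0.219, adjusted p = 1.43e-06). Of the 15 Notch-driven genes 10 fell and 2 rose (camera, adjusted p = 3.51e-05; adjusted p = 0.0875 with an estimated correlation). Dtx1 fell from 5181 ± 407 to 63.86 ± 12.5 scaled reads, Ptcra by 3.53 on the log2 scale and Trib2, a pseudokinase that Notch induces, by 4.44. Notch3 (log2 -1.80), Myc (-1.72), Nrarp (-1.63), Cd3g (-1.22), Hes1 (-1.14), Il2ra (-0.99) and Hes5 (-0.75) fell less, Tcf7 (0.57) and Igf1r (0.67) rose, and Lef1, Hey1 and Heyl did not pass. Genes of the CD3 complex and its signalling went both ways, 9 of 16 lower and 7 higher (camera, adjusted p = 0.0527). The lower ones include Cd3e (log2 -3.18), Cd2 (-3.51), Cd6 (-3.59) and Cd5 (-2.23).

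The cultured ΔDNSe cells also had less RNA of the cell cycle. All 41 S phase genes fell, among them Rrm1, a ribonucleotide reductase subunit (log2 -1.33; camera, adjusted p = 1.05e-21), and 48 of 52 G2 and M phase genes fell and 2 rose, among them Nusap1 (-1.56; adjusted p = 9.43e-23); both lists had adjusted p = 0.0875 with an estimated correlation. The cell cycle inhibitor Cdkn1a (log2 1.47) and the proapoptotic Bbc3 (1.75) were among 6 of 12 p53 target genes that rose, with 1 lower. Genes of IL-7 signalling rose in 12 of 12 cases, including the kinase Pim1 (log2 1.502), Socs3 (1.53) and Mcl1 (1.06) (camera, adjusted p = 7.19e-05; adjusted p = 0.0875 with an estimated correlation). Progenitor genes rose in 9 of 15 cases, with Kit at log2 1.93, Flt3 at 4.01 and Cd34 at 3.87 (adjusted p = 0.000812; adjusted p = 0.181 with an estimated correlation). Innate lymphoid and NK genes rose in 17 of 24 cases and fell in 3, led by the IL-18 receptor chain Il18r1 (4.96), the Fc receptor chain Fcer1g (4.33) and Zbtb16, the PLZF gene (3.22) (adjusted p = 0.00223; adjusted p = 0.264 with an estimated correlation). Mature T cell genes rose in 7 of 7 cases, such as Klf2 (2.03) and Ms4a4b (2.69) (adjusted p = 0.000989; adjusted p = 0.181 with an estimated correlation), and beta selection genes fell in 10 of 16 and rose in 3, with Rorc at -2.59 (adjusted p = 0.00329; adjusted p = 0.181 with an estimated correlation). Over all genes tested, 4906 of 15901 were called higher. Among genes of other cell types, 5 of 8 myeloid (camera, adjusted p = 0.0446) and 3 of 3 mast cell and basophil genes (adjusted p = 0.0407) rose. So did 7 of 11 dendritic genes, with 1 lower (adjusted p = 0.0327). Each list had adjusted p = 0.181 with an estimated correlation. The most abundant members in ΔDNSe were Cebpa (2.32 CPM, 1.445 in WT), Cpa3 (466.3, 69.04) and Bst2 (148.4, 62.17), so the myeloid rises lay near the floor. Xist, an RNA of female cells, averaged 2184 ± 104 CPM in WT and 661 ± 242 CPM in ΔDNSe cultures. Outside the lists, Afdn, a junction protein (-7.30), Rasal1 (-4.50) and Asns, asparagine synthetase (-3.75), fell, and Psg17 (5.77) and Jchain (5.005) rose. By limma, 8275 of 15901 genes passed (4906 higher, 3369 lower), 3021 of them by at least 2-fold, and 7913 passed by edgeR on recovered reads. RLE scaling moved the median log2 fold change of all genes by -0.10 and the share of calls that were higher from 59.3% to 50.4%.

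**Figure D2:**
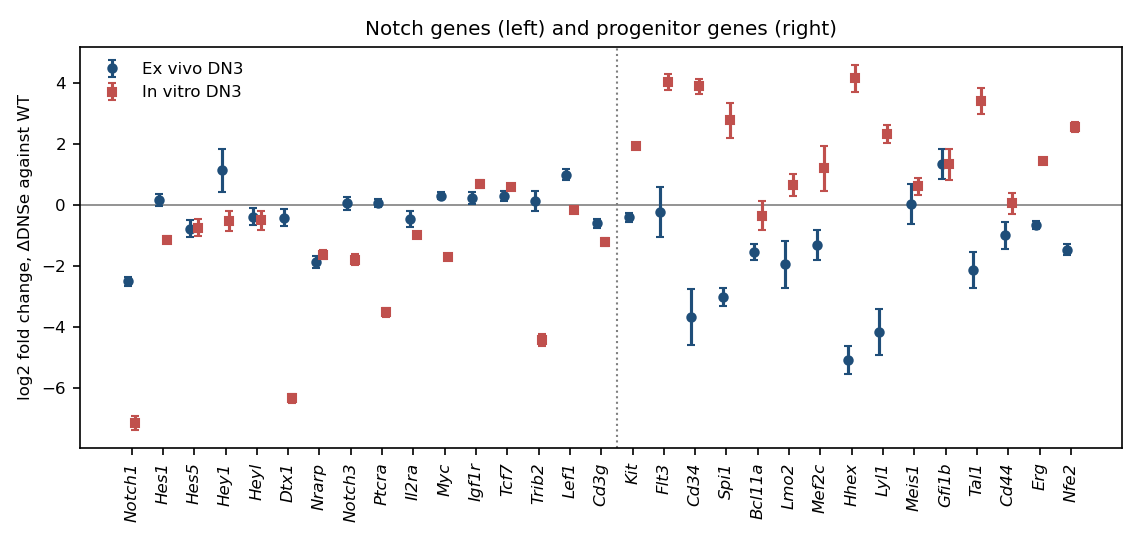
Log2 fold change of ΔDNSe against WT (y axis, error bars of 1 SE) for Notch1 and the Notch-driven genes (left of the dotted line) and for progenitor genes (right) in ex vivo (circles) and in vitro (squares) DN3 cells. Dtx1 was at -0.42 ex vivo and -6.33 in vitro, and Kit at 1.93 in vitro.

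The effect of ΔDNSe on Notch1 was larger in vitro than ex vivo by -4.64 on the log2 scale, and a joint edgeR fit on recovered reads, added after the data were seen, gave -4.61 (adjusted p = 1.69e-06). Over the Notch-driven genes the median difference was -1.14. Dtx1, Ptcra and Trib2 fell in vitro and did not pass ex vivo, while progenitor genes such as Hhex, Spi1 and Nfe2 fell ex vivo and rose in vitro. Across 14520 genes listed in both tables the fold changes had a correlation of 0, and genes are not independent replicates. Among 219 genes called in both, 49 rose in both and 67 fell in both, against 34 and 62.8 for independent lists, 23 rose only ex vivo while falling in vitro, and 80 did the opposite. The joint fit called 4980 of 13813 genes for a difference between the effects. The setting cannot be told apart from the table and library batch it came in.

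**Figure D3:**
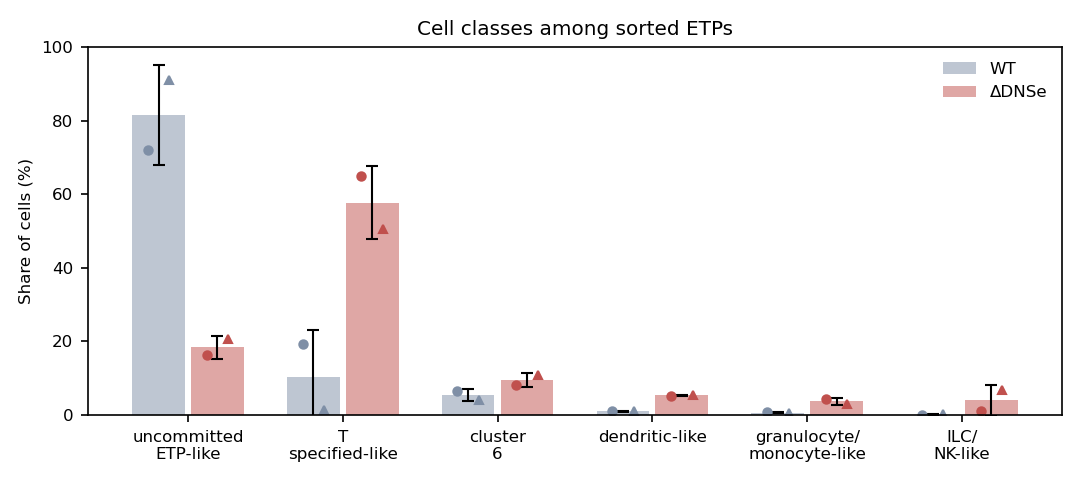
Share of cells in percent (y axis) per cell class (x axis) among sorted ETPs, with bars at the mean of 2 samples, error bars of 1 SD and points per sample (circle, replicate 1; triangle, replicate 2). T specified-like cells made up 10.38% of WT and 57.76% of ΔDNSe cells on average.

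Among cells sorted as ETPs, uncommitted progenitors made up a smaller share and T lineage cells a larger share in ΔDNSe than in WT samples. Shares add up to the whole, so a fall of 1 class raises the shares of the others. Cell numbers per mouse were not analysed. Uncommitted ETP-like cells, with Flt3, Kit and Cd34 among their markers, made up 71.921% (95% interval 70.835 to 72.987) and 91.168% (90.186 to 92.082) of WT cells and 16.198% (15.313 to 17.113) and 20.651% (19.266 to 22.09) of ΔDNSe cells. T specified-like cells, with Bcl11b, the T commitment factor, among their markers, made up 19.323% (18.39 to 20.282) and 1.439% (1.073 to 1.888) in WT and 64.853% (63.683 to 66.011) and 50.667% (48.926 to 52.406) in ΔDNSe. Smaller classes also had larger shares in ΔDNSe, although the labels describe a depletion of myeloid and NK cells before the sort. Dendritic-like cells averaged 1.07% in WT and 5.36% in ΔDNSe, and granulocyte/monocyte-like cells 0.67% and 3.69%. ILC/NK-like cells averaged 0.10% and 3.95%, with 0.978% and 6.915% in the ΔDNSe samples. After thinning, the granulocyte/monocyte-like difference was 0.75 percentage points and a cluster led by Car1, Tspo2 and Klf1, genes of red cell precursors, split off; Car1 and Tspo2 are also among the leading genes of that class in the main clustering. Cluster 6, led by Fgf3 and Zbtb16 and left unnamed, held 5.39% and 9.45%. With 2 samples against 2, an exact permutation test cannot reach p under 0.05, so no p is given; in every class named here both ΔDNSe samples lay on the same side of both WT samples. Different clusters hold most uncommitted cells: 38.91% of WT replicate 1 fell in cluster 1, led by the immediate early genes Egr1 and Fos, and 49.41% of WT replicate 2 in cluster 3, led by interferon-induced genes and Xist. The ETP gate excludes CD25-positive cells, median UMIs per cell ranged from 5470 to 10426, and the difference in T specified-like shares, 47.38 percentage points, became 30.93 at clustering resolution 1.0. For ILC/NK-like cells it was 3.85 and became 2.35 at resolution 0.3.

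Summed over all cells, Notch1 stood at 205.6 and 192.4 CPM in the WT samples and 7.0 and 10.6 CPM in the ΔDNSe samples (log2 -4.52 ± 0.188, adjusted p = 0.0047). Deptor, an mTOR inhibitor (log2 -3.38), Dtx1 (-3.39) and Nrarp (-2.09) fell. Hes1 (-0.89, adjusted p = 0.0643) and Myc (-0.61) did not pass edgeR without a block. Hes1 stood at 205.6 and 166.5 CPM in WT and at 110.9 and 90.1 CPM in ΔDNSe. Myc stood at 98.9 and 133.1 CPM against 64.8 and 87.8. Progenitor genes fell in 12 of 16 cases, and 16 were lower adjusted over the list alone (camera, adjusted p = 2.99e-21; adjusted p = 0.421 with an estimated correlation), among them Hoxa9 (-2.42), Hhex (-1.47) and Flt3 (-1.36). T lineage transcription factors rose in 6 of 18 cases, with 9 higher adjusted over the list alone, such as Gata3 (0.85), Lef1 (1.64), Ets1 (1.35) and Id3 (1.99) (adjusted p = 4.15e-06; adjusted p = 0.421 with an estimated correlation). S phase genes rose in 16 of 41 cases, with 37 higher adjusted over the list alone (adjusted p = 1.32e-18; adjusted p = 0.421 with an estimated correlation). Myeloid S100a9 and Camp, innate Il1rl1 and Zbtb16 and the gamma delta gene Cd163l1 (4.43) rose as well. The antiapoptotic Bcl2 (2.63), the nonclassical class I gene H2-Q7 (2.27), which belongs to a family of near-identical copies, and Ly6d (2.29) were higher. By edgeR, 967 of 13512 genes passed (445 higher, 522 lower), by DESeq2 1724, with no low-count filter 325, and without ΔDNSe replicates 1 and 2 229 and 223. Many more genes passed with the replicate number as a block, as counted in the part on processing. The sums over all cells mix cell classes whose shares differ between the genotypes. Genes of handling stress, summed, stood at 775.8 ± 117 CPM in WT and 346.3 ± 176 CPM in ΔDNSe, with 0 of 11 called (adjusted p = 0.00127; adjusted p = 0.468 with an estimated correlation).

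Within classes, Notch1 fell in each of the 3 classes tested: log2 -4.45 in uncommitted ETP-like cells, -4.56 in T specified-like cells and -4.65 in cluster 6 (adjusted p = 0.000674, 4.72e-12 and 1.81e-06). In uncommitted ETP-like cells, edgeR called 30 of 12352 genes (11 higher, 19 lower), with Deptor (-2.36), Dtx1 (-3.80), Nrarp (-1.38), the transcription factor Maf (-1.22) and the cytokine Ltb (-1.13) lower and Bcl2 (1.55), Ly6d (1.78) and H2-Q7 (2.30) higher. In these cells 38 of 41 S phase genes were higher adjusted over the list alone and 0 over all genes (camera, adjusted p = 4.71e-39; adjusted p = 0.22 with an estimated correlation). The class pools clusters held unequally by the genotypes: cluster 5, led by Hist1h2af and the mitotic kinase Aurkb, held 716 of 4887 and 280 of 3231 uncommitted cells in WT and 390 of 1060 and 151 of 666 in ΔDNSe, and a difference within cells at 1 stage of the cycle was not tested. In T specified-like cells, 166 of 11687 genes passed (61 higher, 105 lower). Il2ra, one of the markers fixed for that class, fell from 323.9 ± 78.3 to 100.3 ± 12.1 CPM (log2 -1.69 ± 0.191, adjusted p = 2.12e-05). Progenitor genes fell in 8 of 14 cases there (adjusted p = 1.12e-19; adjusted p = 0.219 with an estimated correlation), and Ccr9, a chemokine receptor (2.78), Cd163l1 (2.98) and the granzyme Gzma (2.23) rose. Handling stress genes stood at 851 ± 184 CPM in WT and 413.3 ± 297 CPM in ΔDNSe uncommitted cells, 516.2 ± 88.1 and 302.7 ± 132 in T specified-like cells and 531.4 ± 51 and 294.5 ± 142 in cluster 6. Cluster 6 had 32 called genes of 9955, with Il2ra (-2.17) and Deptor (-3.10) lower and H2-Q6 (1.86) and Gzma (1.68) higher. With the replicate number as a block, many more genes passed in each of the 3 classes, as counted in the part on processing. In the T specified-like class, WT replicate 2 gave only 51 cells; the count was 58 by DESeq2, 327 with no low-count filter, 283 without that sample, and 92 and 62 without ΔDNSe replicates 1 and 2. The uncommitted count was 236 by DESeq2, 699 with no low-count filter, 426 and 179 without WT replicates 1 and 2 and 212 and 465 without ΔDNSe replicates 1 and 2, and the cluster 6 count 181 with no low-count filter, 93 without WT replicate 1 and 57 and 62 without ΔDNSe replicates 1 and 2.

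CD19+ cells from the thymus of ΔDNS mice were set beside 3 bone marrow stages to ask which stage they resemble; tissue and genotype differ together in these comparisons. Against proB cells, genes of mature B cells and antigen presentation rose in 15 of 19 cases (camera, adjusted p = 5e-06; adjusted p = 0.666 with an estimated correlation). Cd74, the class II invariant chain, averaged 70630 ± 12400 scaled reads against 868.6 ± 21.3, and Ms4a1, the CD20 gene (log2 6.05), H2-Ab1 (2.68), H2-Aa (3.26) and Cd40 (2.91) rose too. B lineage genes rose in 12 of 17 cases and fell in 3 (adjusted p = 0.00109; adjusted p = 0.666 with an estimated correlation), with Ly6d at 5.24 and Cd72 at 2.59. Dntt, the terminal transferase of early progenitors (-4.04), Erg (-3.23), Kit (-1.22) and Vpreb1, a surrogate light chain gene (-0.83), fell. Notch1 fell by 2.25 on the log2 scale, from 156.6 ± 5.3 to 32.92 ± 4.49 CPM, and of the 15 Notch-driven genes 6 fell and 5 rose, such as Nrarp (-4.08) and Il2ra (3.90). Myeloid genes fell in 13 of 16 cases (camera, adjusted p = 0.00109, and 0.816 with an estimated correlation). Elane, neutrophil elastase, was listed at 0 in both thymic libraries against 332 ± 123 scaled reads in proB. Other granulocyte genes varied widely between marrow replicates: Camp averaged 496.5 ± 668 and Ltf 1329 ± 1800 in proB, and S100a9 5575 ± 7640 in small preB. Mpo varied less (1797 ± 679 in proB). The size of this fall therefore depends on the marrow libraries. The thymic B libraries also stood apart from all marrow libraries in genes that share reads with copies: Acta1 averaged 519.8 ± 83 scaled reads against 1708 ± 240 in proB, the pseudogene Gm11517 1.236 CPM against 44.26 in proB, 51.21 in large preB and 34.82 in small preB, and the pseudogene Gm6525 5.082 CPM against 48.1, 61.7 and 28.72. Histone genes were among the largest rises in these libraries: Hist1h2ap averaged 27400 ± 2500 scaled reads against 395.2 ± 144 in proB (log2 6.16), 525.6 ± 101 in large preB (5.71) and 639.8 ± 425 in small preB (5.59), and Hist1h2ao (6.16), Hist1h2ag (5.55) and Hist1h2ac (5.30) rose against proB. How much of the counts in the 3 thymic comparisons goes with this difference between libraries was not tested. By limma, 9672 of 16169 genes passed (4414 higher, 5258 lower).

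Against large preB cells the thymic B cells differed in 9500 genes (4478 higher, 5022 lower), with Cd74 (log2 6.48), Ly6d (6.12) and Ms4a1 (6.16) higher, Dntt lower (-2.37) and Vpreb1 at -0.19 (adjusted p = 0.2). S phase genes fell in 24 of 41 cases and rose in 4 (camera, adjusted p = 0.00264; adjusted p = 0.872 with an estimated correlation), Mki67, a proliferation marker, stood at -2.16, and Notch1 fell (-1.67). Against small preB cells they differed in 9436 genes (4927 higher, 4509 lower). The surrogate light chain genes Vpreb1 (4.57) and Igll1 (4.24), Dntt (3.04), Cd74 (3.73) and Crhbp (7.73) were higher, and Rag1 (-1.81), the B lineage factor Pax5 (-1.94) and Notch1 (-2.71) lower. S phase genes rose in 31 of 41 cases and fell in 4 (adjusted p = 7e-06; adjusted p = 0.637 with an estimated correlation), with Slbp at 2.34 and Rrm2 at 1.90. Cd40 did not pass against small preB (-0.39, adjusted p = 0.12).

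Within the marrow, large preB cells differed from proB cells in Enpep, the gene of the BP-1 antigen used to sort them (log2 3.47, adjusted p = 0.00511), and in Myl4 (1.85), Cd22 (1.42) and Ikzf3 (1.37), which rose, and Kit (-1.35), Stat4 (-1.25), Adgrg3 (-1.65) and Vpreb2 (-0.67), which fell. Of 15 pro-B and pre-B genes 1 was higher and 2 lower, with 10 lower adjusted over the list alone (camera, adjusted p = 4.5e-05; adjusted p = 0.522 with an estimated correlation). Notch1 stood at -0.58 (adjusted p = 0.0798) and none of the 15 Notch-driven genes passed over all genes or over the list alone. By limma 114 of 16169 genes passed (44 higher, 70 lower), and by edgeR 126 (755 with any count kept), by DESeq2 715, with no filter on low values 63, with pseudocount 0.1 62 and in a fit of only these groups 270. Without large preB replicates 1 and 2 the count was 11 and 10; without either proB replicate limma called 0, where 1330 and 1083 genes had an unadjusted p under 0.05.

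Small preB cells differed from large preB cells in 7037 genes (2986 higher, 4051 lower). The surrogate light chain genes Vpreb1 (log2 -4.76) and Igll1 (-4.41), Dntt (-5.41), Lef1 (-2.60) and Kit (-2.27) fell, and Rag1, the recombinase (2.19), Cd2 (4.53), Ly6d (4.00), Col5a3 (5.03) and Fcmr, the IgM Fc receptor (4.40), rose. All 41 S phase genes fell, among them Mcm6 (-1.96) and Chaf1b (-2.36) (camera, adjusted p = 7.87e-19; adjusted p = 0.371 with an estimated correlation). B lineage genes rose in 14 of 17 cases and fell in 3 (adjusted p = 0.000605; adjusted p = 0.371 with an estimated correlation). Notch1 rose by 1.04, from 104.6 ± 9.44 to 214.8 ± 12.9 CPM (adjusted p = 0.000196), and Il2ra, whose product CD25 was used to sort small preB cells, by 4.00.

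**Figure D4:**
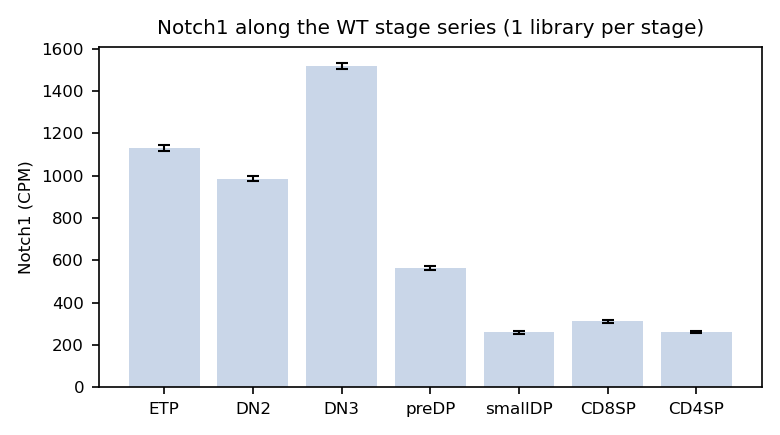
Notch1 level in CPM (y axis) at 7 WT stages (x axis), 1 library per stage, with error bars of the exact Poisson 95% interval that cover counting error only. The DN3 library held 1517 CPM and the CD4 single positive library 261.3 CPM.

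The WT stage series has 1 library per stage and no replicate check, so only levels are given. Notch1 stood at 1129 CPM in ETP, 986.3 in DN2, 1517 in DN3, 562.9 in preDP and 261.2 in small DP cells. CD8 and CD4 single positive cells held 311.7 and 261.3 CPM. Summed over the 16 progenitor genes, levels went from 3464 CPM in ETP to 1423 in DN2 and 120.5 in DN3, with Flt3 at 277.6 CPM in ETP and 1.741 in DN2. Il2ra stood at 109.8 CPM in ETP, 1659 in DN2, 1277 in DN3 and 21.22 in preDP, and Ptcra at 202.3 CPM in DN3. Summed S phase genes held 12130 CPM in preDP and 1758 in small DP cells. By the size rule the stages stood out in Elane and Prtn3, granule proteases (ETP, 252 and 257.5 CPM), Mdga1 and Fgf3 (DN2, 145.9 and 83.05), H19 and Itgb4 (DN3, 206.2 and 83.51), Blk and Rrm2 (preDP, 56.04 and 604.6; Rrm2 not with TMM scaling), Cacna1e and Smoc1 (small DP, 133.3 and 163.7), Itgae (CD8, 670.3) and Zbtb7b, the CD4 lineage factor, and Cd40lg (CD4, 391.4 and 82.53).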

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

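All tests of explanations below were chosen only after the result they concern was seen, except the count over other splits of the in vitro libraries, which was planned.

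Of 31 genes compared between the settings (Notch1, the Notch-driven genes and the progenitor genes), 20 had an effect of ΔDNSe that differed between in vitro and ex vivo DN3 cells in a joint edgeR fit with a term for the difference. For Notch1 itself the in vitro effect minus the ex vivo effect was -4.61 on the log2 scale. Notch-driven genes with a more negative effect in culture were Dtx1 (-5.91), Trib2 (-4.50), Ptcra (-3.62), Myc (-2.06), Notch3 (-1.83), Hes1 (-1.30), Lef1 (-1.15) and Cd3g (-0.64). Progenitor genes differed the other way: Kit (2.30), Flt3 (4.61), Cd34 (8.68), Spi1 (6.10), Lmo2 (3.73), Mef2c (3.08), Lyl1 (7.29), Tal1 (5.96), Erg (2.06), Nfe2 (3.96) and Hhex (10.60). In ex vivo ΔDNSe libraries Hhex averaged 0.495 scaled reads, Lmo2 0.515, Flt3 0.99, Lyl1 2.02, Cd34 2.515, Tal1 5.065 and Spi1 5.545, so the size of these fitted differences depends on the prior count. The setting goes with the deposited table, so it cannot be separated from library handling.

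The first pattern weighed is the set of 413 genes that differed between ΔDNSe and WT ex vivo. A library or alignment difference that the ΔDNSe libraries share with the in vitro libraries is a candidate cause for part of it: 50.6% of the called genes differed at least 2-fold in the called direction between the in vitro and ex vivo WT groups, against 13.8% of all genes tested, although culture also separates those groups. For Notch1 the in vitro table shows a drop of -7.14 between libraries of 1 table, which argues against this cause as the only source of lower Notch1 in ΔDNSe cells. It cannot show how much of the ex vivo change of -2.505 goes with the library difference. Notch1 was also lower in in vitro WT than in ex vivo WT libraries. The lower progenitor genes may reflect fewer ETP and DN2 cells in the ΔDNSe DN3 sort. Genes at least 20-fold higher at those stages had a median of -0.84, and 88.5% had a negative log2 fold change. Only 15 of these 104 genes, all with at least 0.5 CPM in WT, passed. Progenitor genes such as Spi1 (139.5 CPM at ETP, 1.841 at DN3) meet the same rule, so the set is no independent test. The ETP library also held 3209 CPM of summed myeloid genes, so the set does not tell early T cells from myeloid cells. Whether lower Notch1 changes the progenitor genes within DN3 cells was not tested and stays open. How many of the 413 genes go with the difference in sex-linked RNA between ΔDNSe and WT libraries was not tested.

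The second pattern is the larger share of T specified-like cells among ΔDNSe cells sorted as ETPs. Only shares were compared, not cell numbers. A difference in depth per cell is argued against by thinning, after which the shares still differed by 47.22 percentage points. A difference between the replicate 1 and replicate 2 mice was not put to a real test, since each genotype had 1 sample of each number. Within replicate numbers 1 and 2 the shares differed by 45.5 and 49.2 points, and the labels do not say that equal numbers mark a pair. T specified cells with less CD25 may have stayed inside the CD25-negative gate, since Il2ra was lower within that class (log2 -1.69), and this explanation stays open beside a genotype difference in the makeup of the progenitors. After thinning, 16.64% and 18.24% of ΔDNSe T specified-like cells held an Il2ra UMI against 49.28% and 43.14% in WT (unthinned 34.83%, 57.41%, 82.18% and 84.31%) and 0 to 4.55% of granulocyte/monocyte-like cells, whose median depth was 6502 UMIs or more.

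The third pattern is the set of 8275 genes that differed between ΔDNSe and WT in culture. Of the 10 splits of the 6 libraries, 1, the real one, gave that many genes and the highest other split gave 0 (67 to 314 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Of the myeloid and erythroid lists, the most abundant member in the ΔDNSe cultures was Cebpa, at 2.32 CPM against 1.445 in WT. The bounds of this test on myeloid or erythroid cells were set with levels already seen, so its outcome was known and no conclusion is drawn. A first version on all other lineages was replaced because members of the stromal list went both ways. Other lists had abundant members, also expressed in WT cultures: Cpa3 of mast cells at 466.3 CPM against 69.04, Cd163l1 of gamma delta T cells at 936.7 against 210.2, and Gzma of NK cells at 1076 against 852. Innate-like or progenitor-like cells, and fewer dividing cells, stay open as parts of the pattern.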

How the results depend on the processing

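No test in this part was chosen after the result was seen, except TMM scaling, edgeR on recovered reads in place of limma, the gene restrictions of the ex vivo table, the joint edgeR fit and the clustering without Notch, sex, handling and cell cycle genes. Over 301 alternatives, 197 stayed within the replicate spread, within the counting interval for the stage series or within 1.5 times the count. Of the rest, 47 gave fewer calls, 40 gave more and 17 moved by more than the spread or interval. A change of direction was recorded 0 times. Counts of calls and stage levels were labelled by size only, so for them no such change could be recorded. The causes were not tested. The thymic B, in vitro and small preB against large preB counts stayed within 1.5 times under every alternative, and so did the difference of the Notch1 effect between the settings.

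DESeq2 on recovered reads called 24 genes for ΔDNS, 1223 for ΔN1c, 820 for ΔDNSe, 123 for ΔDNS against ΔN1c, 791 for ΔDNSe against ΔDNS and 715 for large preB against proB. For the same comparisons edgeR with any count kept called 13, 826, 715, 67, 607 and 755. With no filter on low values, ΔN1c had 136, ΔDNS against ΔN1c 11 and large preB 63, and with pseudocount 0.1 the last pair had 3 and 62. Fits of only the groups compared gave 6 for ΔN1c, 230 for ΔDNSe, 134 for ΔDNS against ΔN1c, 1142 for ΔDNSe against ΔDNS and 270 for large preB. Genes within 2-fold between the WT groups gave 110 for ΔDNSe, 2 for ΔDNS against ΔN1c and 132 for ΔDNSe against ΔDNS, and without pseudogenes and unnamed gene models ΔDNS had 4. Leaving out each replicate in turn gave 6 to 117 genes for ΔDNS, 2 to 898 for ΔN1c, 112 to 772 for ΔDNSe, 1 to 36 for ΔDNS against ΔN1c, 103 to 179 for ΔDNSe against ΔDNS and 0 to 11 for large preB; where this leaves 1 library in a group, that library is assumed to vary like the other groups.

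In the single-cell sums DESeq2 called 1724 genes over all cells, 58 in T specified-like and 236 in uncommitted ETP-like cells. With no low-count filter the counts were 325, 327 and 699, and 181 in cluster 6. Leaving out each sample in turn gave 223 to 1363 over all cells, 62 to 283 in T specified-like cells, 41 to 93 in cluster 6 and 179 to 465 in uncommitted ETP-like cells. At resolution 0.3 the difference of the shares was -47.23 percentage points for uncommitted ETP-like cells, 3.04 for dendritic-like cells and 8.39 for the other lineages together; at resolution 1.0 it was 30.93 for T specified-like and 4.54 for dendritic-like cells. After thinning it was -46.02 for uncommitted, 3.95 for dendritic-like, 0.75 for granulocyte/monocyte-like cells and 8.7 for the other lineages. For dendritic-like cells it was 3.48 with doublets kept, 4.09 with a fixed minimum of 1000 UMIs and 4.51 with the reduced variable genes. TMM scaling moved Notch1 in the stage series to 1057 CPM in ETP, 931.8 in DN2, 1473 in DN3, 600.8 in preDP and 331.9 in CD8 cells.

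With an estimated correlation no gene list passed (0 in each set of list tests), against 4, 4, 4, 6, 4, 12, 4, 5, 6, 5 and 7 lists in the bulk and 18, 8, 10 and 10 in the single-cell comparisons with the preset one; at an unadjusted p under 0.05 it gave 0 to 4 lists per comparison, and fry called 0 for ΔDNS, 2 for ΔN1c, 3 for ΔDNSe, 0 between the deletions, 21 of 23 in vitro, 14, 13 and 14 for thymic B against proB, large preB and small preB, 0 for large preB against proB, 14 for small against large preB and 0 in the single-cell comparisons.

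The labels do not say that equal replicate numbers mark a shared litter, batch or day, although the deposited marker tables set same-numbered single-cell samples side by side. Deviations of same-numbered libraries correlated at -0.092 to 0.256 in the ex vivo table, -0.157 to -0.007 in vitro, -0.405 to 0.366 in the B lineage table and 0.649 for the single-cell samples, whose Xist RNA also goes with the number. With the replicate number as a block the counts were 9 for ΔDNS, 117 for ΔN1c, 521 for ΔDNSe, 4 for ΔDNS against ΔN1c, 579 for ΔDNSe against ΔDNS, 7641 in vitro, 9511, 9314 and 9261 for thymic B against proB, large preB and small preB, 65 for large preB against proB and 6763 for small against large preB. In the single-cell sums the block gave 4585 over all cells, 466 in T specified-like, 423 in cluster 6 and 3080 in uncommitted ETP-like cells. In simulations with 200 changed genes, small changes were recovered unequally. At 1.5-fold, the main test found 14% of the changed genes ex vivo (15190 genes) and 56% in vitro (15574 genes). It found 10% for thymic B against proB (15987 genes) and 4% in the single-cell sums (13377 genes). Far more genes passed in the real in vitro and thymic B comparisons, which eases the adjusted p threshold, so these rates do not carry over to them.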

Other observations

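No test of an explanation is reported in this part, and the genes named beyond the fixed lists were chosen only after their values were seen. Receptor segments could be read only in the single-cell data. Summed over all ETP-sorted cells, 2 of 10 T cell receptor gamma segments rose in ΔDNSe and 9 were higher adjusted over the list alone (camera, adjusted p = 8.2e-09; adjusted p = 0.421 with an estimated correlation), with Trgv2 at a log2 fold change of 2.43 and Tcrg-C1 at 149.1 ± 82.5 CPM in WT and 578.2 ± 29.5 CPM in ΔDNSe (adjusted p = 0.0509). Genes of T cell receptor signalling rose in 3 of 16 cases and fell in 2 (camera, adjusted p = 0.0273; adjusted p = 0.421 with an estimated correlation), with Itk (2.50), Cd28 (1.88) and Zap70 (1.30) higher and Cd6 (-1.18) and Cd27 (-0.82) lower. Dntt stood at 0.21 (adjusted p = 0.564). All of these sums pool cell classes whose shares differ between the genotypes. Within T specified-like cells, uncommitted ETP-like cells and cluster 6, 0 of 8, 0 of 4 and 0 of 4 gamma segments passed. Adjusted over the list alone, 1, 4 and 1 were higher. Of the signalling genes, 1 of 15 rose and 2 fell in T specified-like cells, and 0 of 14 passed in uncommitted ETP-like cells.

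In culture, gamma delta T cell genes went both ways in ΔDNSe: Cd163l1 (log2 2.18), Maf (1.59) and Sox4 (0.87) rose and Etv5 (-0.80) and Sox13 (-0.53) fell, 4 of 8 each way. Bcl11b (0.22, adjusted p = 0.136), Gata3 (-0.02) and Rag1 (0.36) did not pass there. Among ex vivo ΔDNS libraries, 0 of 41 S phase and 0 of 52 G2 and M phase genes passed by limma or over the list alone, while camera called both lists lower at adjusted p = 5.68e-11 and 4.85e-13 (adjusted p = 0.693 with an estimated correlation for both).

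Gsr averaged 20.55 ± 4.5 CPM in ΔN1c and 125.7 ± 3.97, 101.1 ± 2.25 and 147.8 ± 15.9 CPM in WT, ΔDNS and ΔDNSe DN3 cells. Mid1 averaged 5.6 ± 2.97 CPM in WT, 471.1 ± 118 in ΔDNS, 34.32 ± 3.05 in ΔN1c and 207.4 ± 1.77 in ΔDNSe libraries ex vivo, and 316 ± 11.6 in WT and 99.98 ± 8.4 in ΔDNSe cultures. H2-Q7, one of a family of near-identical genes, averaged 20.11 ± 5.49 CPM in WT and 92.02 ± 15.3 in ΔDNSe cultures. In the single-cell samples Xist stood at 0.02342 and 2291 CPM in WT replicates 1 and 2 and at 0.02505 and 2027 CPM in ΔDNSe replicates 1 and 2.

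The authors' deposited table of cluster markers lists 13 clusters with 3356 gene entries for replicate 1 and 12 clusters with 3132 for replicate 2, and Notch1 in 0 of them. In the authors' deposited table for replicate 1, cluster 0 carried Bcl11b at a log2 fold change of 1.91 in WT and 1.01 in ΔDNSe, Ly6d at 2.32 and 1.29 and Il2ra at 1.204 and 0.44, and cluster 11 carried Prtn3 at 5.30 and 5.33. These fold changes set a cluster against the other cells of the same sample, so they do not compare the genotypes.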
